A study of Tropheryma whipplei with 9 samples.

How the data were processed

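Untreated and doxycycline-treated cultures of T. whipplei were compared on 9 two-colour arrays, 3 for each of control, MIC and 10xMIC. Per the labels' protocols, RNA came from at least 3 independent cultures per condition, was reverse transcribed, and its cDNA was amplified with the GenomiPhi kit and random primers before labelling. Amplification can change the relative abundance of transcripts. Per the labels, the untreated reference carried Cy3 and the sample Cy5 on every array, so no dyes were swapped. The image names in the file headers tied the same dye to the same scan channel on 9 of 9 arrays. They do not show which RNA each dye labelled. Whether the reference was one pool of RNA is not given in the sources used here.

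Per the file headers, the spot intensity of each channel is the output of QuantArray software, with its adaptive method and no background subtraction. The deposited intensity is a linear brightness with its local background beside it and a mark for spots the software ignored. The Cy5 columns have the same form as the Cy3 columns. The deposited value table holds log2 ratios of Cy5 over Cy3, made by the authors in spreadsheet software, with spots left out, per the labels, when dim in both channels. Its scale and direction were found from the scanner values: slopes of the deposited log2 values on the background-subtracted log2 ratio of the same array were 0.988 to 1.08, with r from 0.967 to 0.999. The offset between them varied by 0.018 or less over 4 classes of intensity, so the table showed no intensity-dependent correction. Each array of the table was centred near 0, with medians of -0.02, -0.02 and -0.02 for control replicates 1 to 3, 0.00032, -0.0053 and -0.02 for MIC, and -0.02, 0.01 and -0.0097 for 10xMIC. How it was centred is not given in the sources used here. The spots ignored by the scanner software were blank in it on all arrays.

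The name column of the scanner files was empty and no annotation was used here, so no spot was given a gene. The tests of gene lists fixed before the data were examined, and the genes to be named from them, were not run for that reason. The slide has 12 by 4 blocks of 6 by 16 spots. The design text gives 4 technical replicates per array. Neighbouring spots of an odd and the next even number differed by a median of 0.044 in the deposited log2 ratio, against 0.22 between such pairs, and spots 2304 numbers apart by 0.084. A probe was therefore taken as 2 neighbours in the upper and 2 in the lower part of the slide. Of the 1152 features, 291 had no kept spot on any array, 70 were measured on too few arrays, and 2 were set aside because the deposited table left them blank on every array. The choice to set those 2 aside was made after their values were seen.

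Intensities were background-corrected with normexp (offset 50) and normalized within each array by global loess, with weight 0 for ignored spots and for spots whose net signal was under 2 times the background in both channels. Between 0 and 166 spots per array were dim in this sense. Loess centres each array, so a change in the total amount of RNA cannot be seen. The spots of a probe were averaged on each array, and a probe was tested if measured on at least 2 arrays of every group. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), with 1 mean per group, and p-values were adjusted by the Benjamini-Hochberg method in each contrast. A probe counted as changed at an adjusted p under 0.05. The contrasts were MIC minus control, 10xMIC minus control and 10xMIC minus MIC. Setting treated against control-versus-control arrays cancels a constant dye effect. In the control group, 68 of 789 probes had a log ratio different from 0, between -0.55 and 0.52, with 0 beyond 1.5-fold. Without a dye swap, a dye effect and a difference between the control samples and the reference cannot be told apart there.

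Before averaging, replicates were compared by whether their difference in the upper part of the slide recurred in the lower part. Control arrays 1 and 2 showed no recurring difference, so their mean entered as 1 sample and the fit used 8 samples. The fit planned before the data were examined kept them as 2. This change was made after counts under several settings had been seen, and it lowered them: kept apart, the counts were 463, 338 and 480 in the order of the contrasts, against 392, 239 and 444. The difference between 10xMIC replicates 2 and 3 recurred weakly (r = 0.16, 95% confidence interval 0.09 to 0.23), and they stayed separate. The image name of the Cy5 scan of 10xMIC replicate 3 carried the slide code of replicate 2. The median Cy5 intensities of these arrays differed (14232 in replicate 3, 17258 in replicate 2). That does not exclude another scan of the same slide.

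Named probes were chosen by a rule written before the data were examined: the highest and lowest log2 fold changes among changed probes whose arrays of one group all lay on the same side of the other group. The rule allowed more, but for want of gene names it was limited to 2 probes that rose and 2 that fell in each contrast. Quantification day (4 days) and experiment code (6 codes) were read from the file headers as batches. Days were fitted as a block, and each day that held several groups was set against a fit to the samples of the other days, a check added after the data were seen. Experiment codes were fitted as a random block with duplicateCorrelation (statmod 1.5.0), which gave a consensus correlation of 0.83. The only codes with several samples were that of the control slides and that of replicates 2 and 3 at the higher dose. The correlation rests on these samples, and those replicates 2 and 3 may not be independent. No code was shared between groups, and the counts with this block depend on that correlation. Shared controls were simulated 200 times, and the covariance was computed again with a separate control sample for each dose, a check added after the data were seen. Other alternatives concerned background correction, normalization, spot filters, spot averaging, the deposited values, single channels after quantile normalization, the variance model, array weights and leaving out each array.

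The procedure was checked on simulated spots with the real brightness and known changes at 200 probes per dose, over 789 probes. For MIC minus control it found 93 of 100 probes changed by 0.4 on the log2 scale, 100 of 100 changed by 1, and called 7 of 589 unchanged probes. For 10xMIC minus control the numbers were 90 of 100, 100 of 100 and 3 of 589. For 10xMIC minus MIC they were 162 of 164, 160 of 160 and 6 of 439. These counts hold only for the array noise that was simulated. They do not give the rate of false calls on the real arrays. There, experiment code as a random block gave a consensus correlation of 0.83, which rests on the few codes with several samples.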

Results

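Transcript levels were measured in Tropheryma whipplei strain Twist, the slow-growing actinobacterium that causes Whipple's disease, after exposure to doxycycline. Doxycycline is a tetracycline that binds the small ribosomal subunit and blocks the entry of aminoacyl-tRNA. Cultures grown without host cells for 12 days received the drug for 6 h at its minimum inhibitory concentration (MIC, 0.5 µg/µl in the units the labels use) or at 10 times that concentration (10xMIC, 5 µg/µl), or received none. Whether the untreated cultures were held for the same 6 h is not given in the sources used here. Each of the 9 arrays compared a Cy5-labelled sample with Cy3-labelled RNA of untreated culture, after the cDNA of both had been amplified. There were 3 arrays of untreated culture against untreated culture (control), 3 of MIC cultures and 3 of 10xMIC cultures, which the labels describe as 3 biological replicates per condition. A positive log2 ratio means more signal in the sample than in the untreated reference.

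The spots of an array were read here as 1152 features of 4 spots each, of which 789 were measured often enough to be tested. The files used here do not pair spots with genes, so features are called probes and are identified by the number of their first spot, as in S45 for spot 45. Between 2970 and 3147 spots per array entered the fit. The median Cy3 intensity lay 6.81 to 42.2 times above the median Cy3 background, and the median Cy5 intensity 6.68 to 95.5 times above its own. These ratios were lowest on the MIC arrays, at 6.81 to 8.26 in Cy3 and 6.68 to 8.05 in Cy5. On control arrays they were 17.6 to 42.2 and 20.3 to 95.5, and on 10xMIC arrays 9.96 to 21.2 and 8.05 to 18.0. Signal over background thus differed with the group and cannot be separated from it. The number of arrays limits the precision.

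Control arrays 1 and 2 differed by less than the measurement noise and were counted as 1 sample. Their difference in the upper part of the slide did not recur in the lower part (r = -0.04 across probes, 95% confidence interval -0.11 to 0.03), whereas r was 0.31 for controls 1 and 3 and 0.25 for controls 2 and 3. The control group therefore held 2 samples and each dose 3. Log ratios spread little on the control arrays, with an SD across probes of 0.145 to 0.158, and more on the MIC arrays (0.343 to 0.388) and the 10xMIC arrays (0.278 to 0.370). Arrays of one group resembled each other across probes, with r from 0.81 to 0.91 in the control group, 0.92 to 0.94 at MIC and 0.71 to 0.97 at 10xMIC. Between MIC and 10xMIC arrays r was 0.18 to 0.35, and between control and treated arrays 0.05 to 0.27. Replicate 1 at 10xMIC stood apart from replicates 2 and 3 (r = 0.71 with each), which correlated with each other at 0.97.

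**Figure D1:**
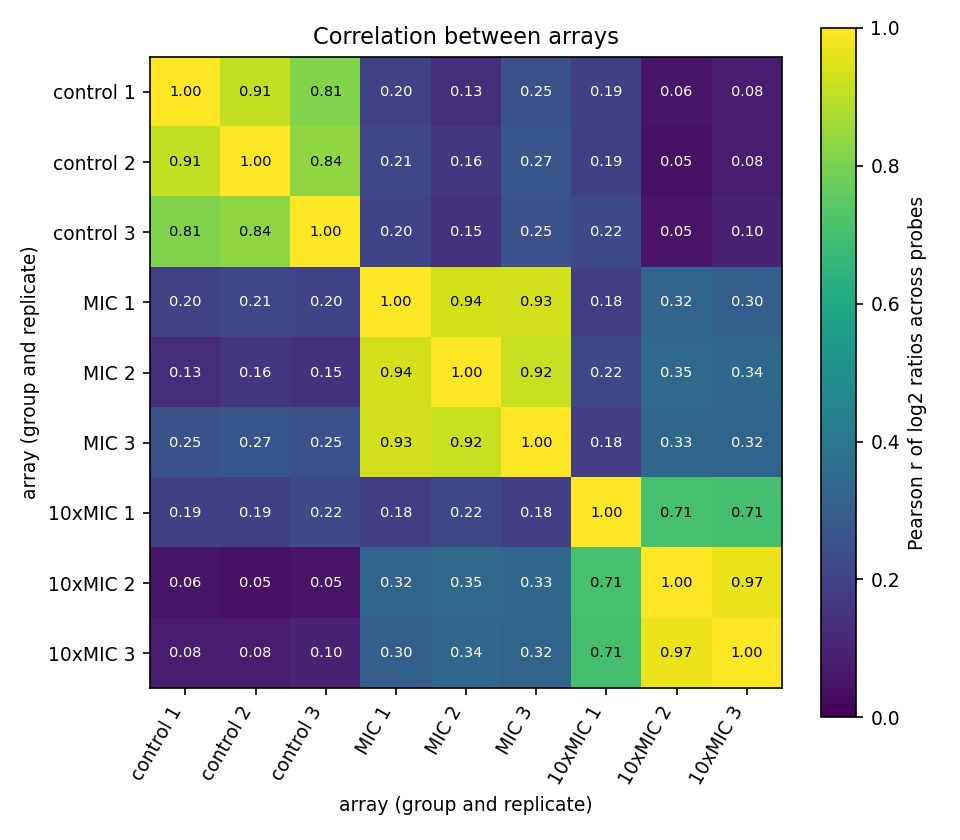
Pearson correlation of log2(Cy5/Cy3) across tested probes for each pair of the 9 arrays, with arrays named by group and replicate on both axes and r printed in each cell. Arrays of one group form the bright blocks along the diagonal, MIC arrays at 0.92 to 0.94, and r between MIC and 10xMIC arrays is 0.18 to 0.35.

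The first comparison asked which transcripts differed after 6 h at the MIC. Of the 789 probes, 392 changed (limma, Benjamini-Hochberg adjusted p under 0.05), 207 of them higher and 185 lower than in the control. Most changes were small. The median size among changed probes was 0.41 on the log2 scale, or 1.33-fold, and only 38 rose and 31 fell by 1.5-fold or more. Changes of 2-fold or more were measured at 4 probes, 2 higher and 2 lower.

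Probe S1593 (block row 5, block column 1) rose the most, by 2.41-fold, with a log2 ratio of 1.33 ± 0.23 (SD, n = 3) at MIC against 0.06 ± 0.10 (SD, n = 2) in the control. Its log2 fold change was 1.27 (SE 0.13, adjusted p = 0.000176, limma). In the Cy5 channel alone its change was 0.69 (adjusted p = 0.10), and in the Cy3 reference channel alone -0.93 (adjusted p = 0.14). Probe S1775 (block row 5, block column 3) followed at 0.75 ± 0.03 (SD, n = 2 of the 3 MIC arrays) against -0.31 ± 0.03 (SD, n = 2), a log2 fold change of 1.05 (SE 0.07, adjusted p = 0.000121, limma). That difference lay in the reference channel: the Cy5 signal alone differed by 0.07 (adjusted p = 0.83) and the Cy3 signal alone by -0.99 (adjusted p = 0.022). Probe S45 (block row 1, block column 1) fell 2.10-fold, from -0.17 ± 0.0030 (SD, n = 2) in the control to -1.24 ± 0.14 (SD, n = 3), a log2 fold change of -1.07 (SE 0.08, adjusted p = 0.000122). Probe S1021 (block row 3, block column 3) fell 2.09-fold, from 0.08 ± 0.03 (SD, n = 2) to -0.98 ± 0.15 (SD, n = 3), with a log2 fold change of -1.06 (SE 0.09, adjusted p = 0.000129). For S45 and S1021 the Cy5 channel alone gave changes of -0.91 and -1.41 (adjusted p = 0.015 and 0.026).

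At 593 probes, or 75.2%, every MIC array lay on one side of both control samples, where chance gives 20%. The arrays were quantified on 4 days, and with the day as a block, which leaves 2 residual degrees of freedom in place of 5, 186 probes changed. On the 1 day that held all groups, the MIC array differed from the control sample in the same direction as on the other days at 49 of the 49 probes called from the other days alone, and r between these fold changes was 0.91 across probes. Those calls rest on 2 MIC samples and 1 control sample, assumed to vary like the other groups. The Cy5 channel alone called 53 probes, 13 higher and 40 lower, and without control replicate 3, which leaves 1 control sample, 238 changed. All control slides had an experiment code of their own in the file headers, so a batch marked by that code and the control group cannot be told apart. With the code as a random block 231 probes changed, a count that depends on a correlation estimated from the few codes with several samples.

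The second comparison asked the same at 10 times the MIC. Of the 789 probes, 239 changed, 124 of them higher and 115 lower than in the control. Their median size was 0.36 on the log2 scale, or 1.28-fold. The larger changes were mostly increases: 27 probes rose and 8 fell by 1.5-fold or more, and 6 rose and 0 fell by 2-fold or more.

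Probe S2103 (block row 6, block column 2) rose 4.72-fold, from -0.07 ± 0.04 (SD, n = 2) in the control to 2.17 ± 0.22 (SD, n = 3), a log2 fold change of 2.24 (SE 0.12, adjusted p = 1.06e-05, limma). At MIC the same probe had a log2 fold change of 0.33 (SE 0.12, adjusted p = 0.0496). Probe S139 (block row 1, block column 2) rose 3.75-fold, with a log2 ratio of 1.90 ± 0.36 (SD, n = 3) against -0.0043 ± 0.02 (SD, n = 2) and a log2 fold change of 1.91 (SE 0.18, adjusted p = 0.000155). Its change at MIC was 0.06 (adjusted p = 0.80). Among decreases, S1021 fell 1.89-fold, by a log2 fold change of -0.92 (SE 0.09, adjusted p = 0.000203). It also fell at MIC. Probe S805 (block row 3, block column 1) fell 1.67-fold, with a log2 fold change of -0.74 (SE 0.17, adjusted p = 0.012). At MIC its log2 fold change was -0.43 (SE 0.17, adjusted p = 0.067), and its MIC values of -0.43, -0.61 and -0.46 lay below both control samples. Its 10xMIC values were -1.25, -0.64 and -0.56 in replicates 1 to 3. In the Cy5 channel alone these 4 probes changed by 1.42, 1.38, -1.21 and -0.996 in the order named, each with an adjusted p of 0.041 or less.

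At 495 probes, or 62.7%, every 10xMIC array lay on one side of both control samples, where chance gives 20% for independent samples. The chance share is higher if 10xMIC replicates 2 and 3 are not independent. The count of changed probes depended more on the setting here than in the other comparisons. Control replicate 3 and 10xMIC replicate 2 were each alone on their quantification day, so a day block leaves 1 control sample in the contrast. With the quantification day as a block 9 probes changed, all 9 higher, and S139 (log2 fold change 1.96, adjusted p = 0.052), S1021 (-0.89, adjusted p = 0.056) and S805 (-0.69, adjusted p = 0.16) missed the threshold. Within the 1 day that held all groups, the direction was that of the other days at 17 of the 17 probes called from the other days alone (r = 0.86 across probes), calls that again rest on 1 control sample. They also rest on 10xMIC replicate 2, which is close to replicate 3 of that day (r = 0.97) and may not be independent of it. Without control replicate 3, 78 probes changed and S805 missed the threshold (log2 fold change -0.77, adjusted p = 0.077). With the experiment code as a random block 56 probes changed, again with a correlation estimated from the few codes with several samples. The Cy5 channel alone called 38. Counts were higher when arrays were scaled to one spread (389), weighted by quality (498), or compared with 0 in place of the control arrays (404).

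**Figure D2:**
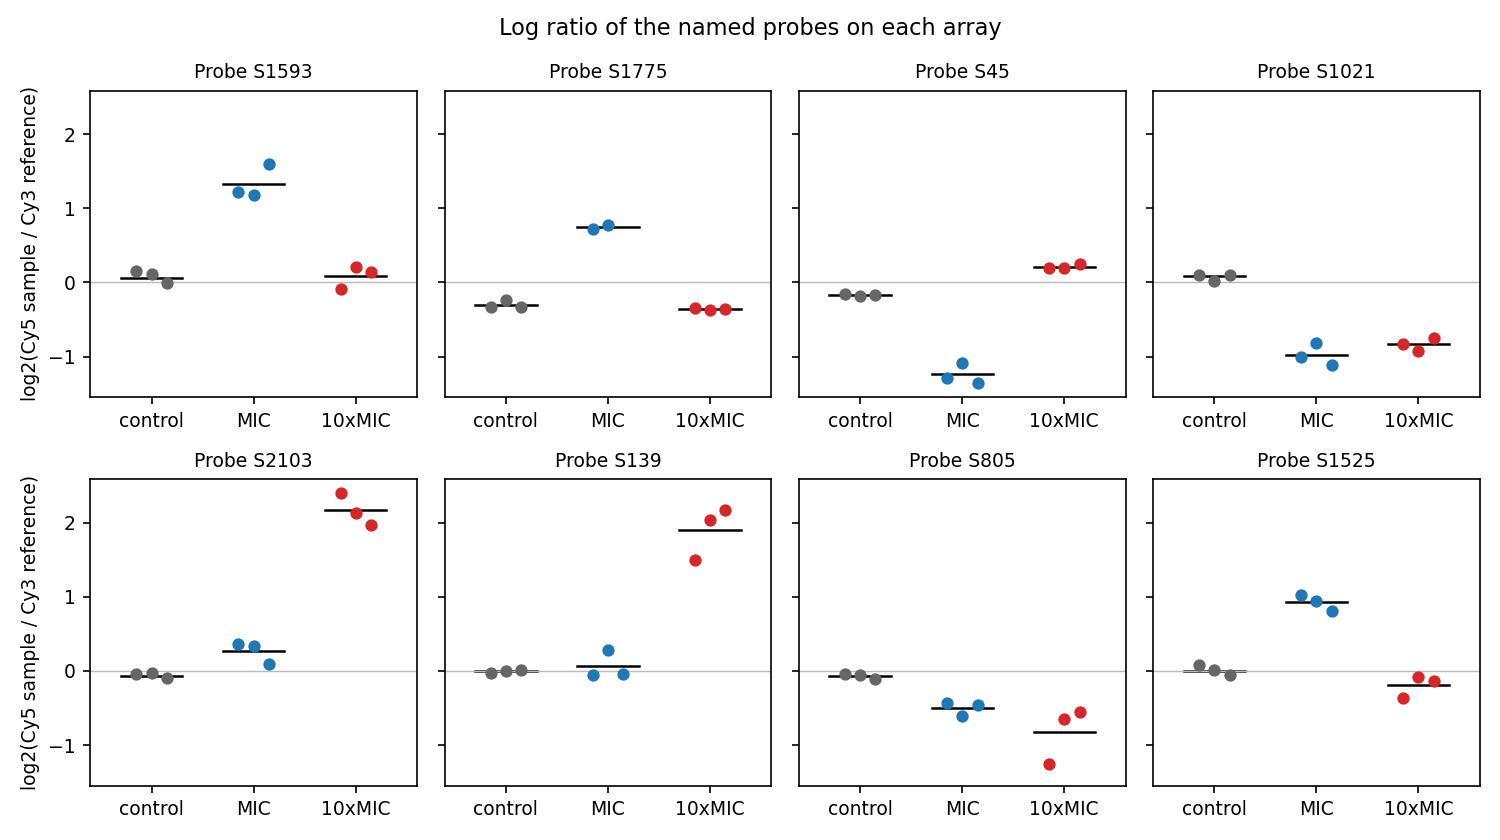
Log2(Cy5/Cy3) of the 8 named probes on each array (points; S1775 was not measured on 1 MIC array) by group on the x axis, with lines at group means in which control arrays 1 and 2 count as 1 sample. S2103 and S139 stand at 2.17 and 1.90 on average at 10xMIC, and S45 at -1.24 at MIC and 0.21 at 10xMIC.

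The third comparison set the doses against each other, without the control arrays in the contrast. Of the 789 probes, 444 differed between 10xMIC and MIC, 219 of them higher and 225 lower at 10xMIC, with a median size of 0.39 on the log2 scale. By 1.5-fold or more, 43 were higher and 46 lower, and by 2-fold or more 7 were higher and 4 lower. S2103 and S139 were 3.75-fold and 3.59-fold higher at 10xMIC, with log2 fold changes of 1.91 (SE 0.11, adjusted p = 5.51e-06, limma) and 1.84 (SE 0.16, adjusted p = 2.89e-05). S1593 was 2.37-fold lower (log2 fold change -1.24, SE 0.12, adjusted p = 4.66e-05), since it lay at 0.09 ± 0.16 (SD, n = 3) at 10xMIC, near its control level. Probe S1525 (block row 4, block column 4) was 2.18-fold lower (-1.12, SE 0.09, adjusted p = 2.04e-05), with a log2 ratio of 0.93 ± 0.11 (SD, n = 3) at MIC and -0.19 ± 0.15 (SD, n = 3) at 10xMIC. In the Cy5 channel alone the difference was -0.66 for S1593 (adjusted p = 0.088) and -0.58 for S1525 (adjusted p = 0.031). In the Cy3 reference channel alone it was 0.98 for S1593 (adjusted p = 0.077) and 0.58 for S1525 (adjusted p = 0.049).

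At 498 probes, or 63.1%, all arrays of one dose lay on one side of all arrays of the other, where chance gives 10% for independent samples. The chance share is higher if 10xMIC replicates 2 and 3 are not independent. With the quantification day as a block 344 probes differed. Within the day that held all groups, the direction was that of the other days at 225 of the 225 probes called from the other days alone (r = 0.88 across probes), with the same limit on replicates 2 and 3. Within the day that held MIC replicates 1 and 2 and 10xMIC replicate 1, it was so at 470 of 534 (r = 0.78), called from 1 MIC sample and 10xMIC replicates 2 and 3, whose closeness can raise the number of calls. The Cy5 channel alone called 77 probes, 46 higher and 31 lower. No experiment code was shared by MIC and 10xMIC arrays, so a batch marked by that code and the dose cannot be told apart. With the code as a random block 336 probes differed, a count with the same dependence on the few codes with several samples.

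Across the 789 probes, 131 changed against control at both doses, 107 of them in the same direction and 24 in opposite directions. Higher at both doses were 55 probes, where independent lists of these lengths would share 32.5, and lower at both were 52, against 27.0. Higher at MIC and lower at 10xMIC were 14, against 30.2, and lower at MIC and higher at 10xMIC were 10, against 29.1. Without control replicate 3 the number in opposite directions was 5, and with the quantification day as a block 0 by limma (12 at unadjusted p under 0.05 for both doses). The difference between doses was itself past the threshold at 41 of the 107 that moved the same way, at 216 of the 261 changed at MIC alone and at 83 of the 108 changed at 10xMIC alone. Over all 789 probes it was so at 444, and selecting probes called at 1 dose alone favours such a difference. The fold changes at both doses correlated across probes with r = 0.33 (Spearman's rho 0.34), and probes are not independent replicates. Because both used the same control arrays, 200 simulations of unchanged groups gave r = 0.60, with a mean of 0.0050 shared calls in each direction. The covariance of the fold changes was 0.0343, against 0.00574 in the simulations, a difference of 0.0285. With each dose set against a control sample of its own, controls 1 and 2 for one and control 3 for the other, the covariance was 0.0334 or, the other way round, 0.0317, and r was 0.32 or 0.30. A deviation common to all control slides would remain in these values. The overlap of calls was not recounted in this way, so part of its excess may come from the shared controls.

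**Figure D3:**
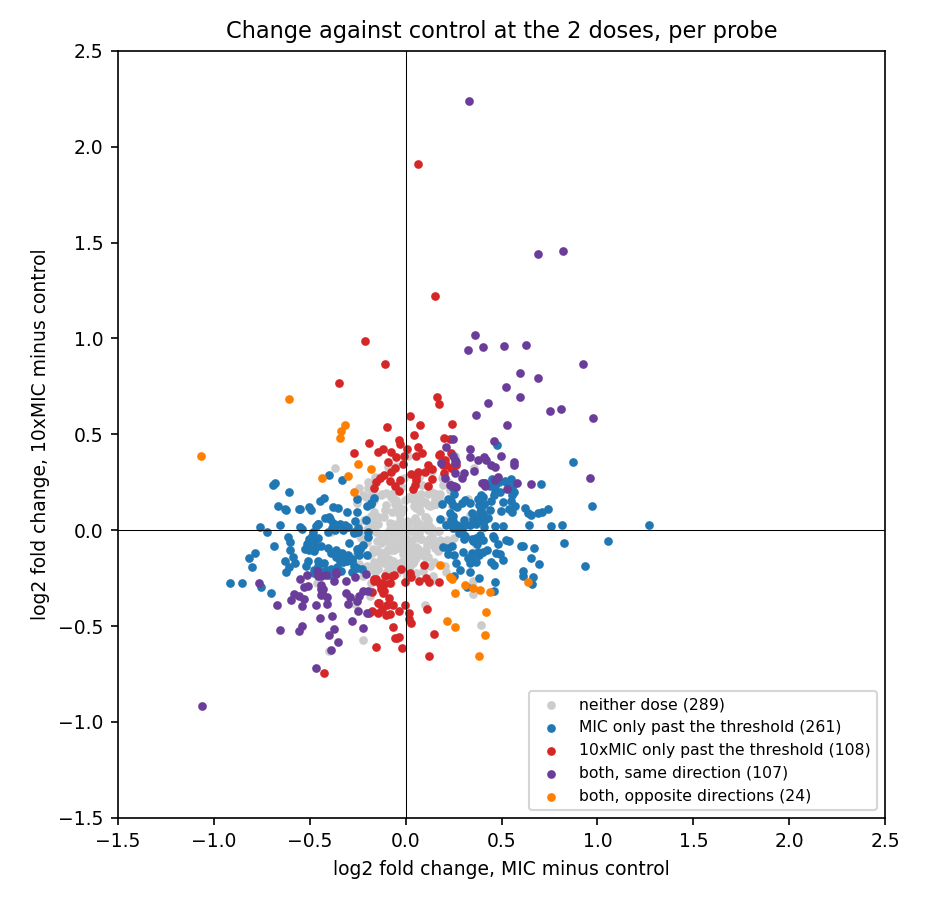
Log2 fold change against control at MIC (x axis) and at 10xMIC (y axis) for each of the 789 tested probes, coloured by the dose or doses at which the adjusted p was under 0.05. The 107 probes that changed the same way at both doses lie in the upper right and lower left quadrants, and the 24 that changed in opposite directions in the other quadrants.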

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

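The tests of a separate control batch and of the Cy3 reference and the recount of opposite directions under other settings were chosen after the result was seen, as was the attention to the 2 blank features; the test between parts of the slide and the splits of the samples were set before.

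At 24 probes the change against control was past the threshold at both doses but in opposite directions. The direct comparison of the doses was past the threshold at each of them, which their selection makes nearly certain and so adds no support. The number was 5 without control replicate 3, 4 with the experiment code as a random block, and 0 by limma with the quantification day as a block or in the Cy5 channel alone (12 and 2 at unadjusted p under 0.05 for both doses). Over 30 alternatives it ranged from 0 to 82. Probe S45, which fell by 1.07 at MIC and rose by 0.39 at 10xMIC on the log2 scale (adjusted p = 0.000122 and 0.0084, limma), had the largest gap of them, 1.46.

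In data left out of the comparisons, 2 adjacent features (block row 3, block column 4, spot row 1), bright and kept by the scanner software but blank in the deposited table on every array, gave higher ratio changes than every tested probe at both doses. Their log2 fold changes against control were 2.25 and 1.95 at MIC and 4.50 and 4.36 at 10xMIC. The unnormalized Cy5 intensity of the first was 12123 to 29158 on control arrays, 8120 to 15415 at MIC and 45429 to 65101 at 10xMIC, and that of the second 12952 to 31886, 11591 to 18071 and 45815 to 61832. It was thus not higher at MIC than on control arrays. The highest value, 65101, lies near the scanner's ceiling, so the 4.50 of the first may be understated. The Cy3 reference intensity of both was lower on treated arrays (2233 to 5998) than on control arrays (6923 to 14550). What these spots hold is not given in the sources used here.

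The fold changes against control could come from the reference, the slides or the treatment. Uneven hybridization over the slide is argued against by the correlation of fold changes between the upper and lower parts of the slide, at least 0.939 across probes at both doses. A shift in the untreated Cy3 reference is argued against as the main source at 10xMIC, where Cy3 carried 0.172 (SE 0.025) of the change over the changed probes, but stays open as part of it at MIC, where the share was 0.341 (SE 0.028). These shares are taken over probes, which are not independent replicates, so the SEs may understate the uncertainty between slides. A separate hybridization batch of the control slides alone would shift both doses alike. It is argued against as the whole source, since the change differed between the doses at 281 of the 392 probes changed at MIC. Over all 789 probes the doses differed at 444. Batches of the treated slides stay open, because MIC and 10xMIC slides share no experiment code either. They could make the doses differ by themselves. As part of the source a control batch stays open, because 0 treated arrays share the control slides' experiment code. An effect of doxycycline also stays open, as does a difference between cultures, including in how long they were incubated.

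For MIC minus control, 1 of the 10 splits of the 5 samples, the real one, gave as many as 392 changed probes, and the highest other split gave 1 (158 at an unadjusted p under 0.05, against 441 in the real split). For 10xMIC minus control the real split, 1 of 10, gave 239 and the highest other 36 (210 at an unadjusted p under 0.05, against 347). For 10xMIC minus MIC the real split of the 6 samples, again 1 of 10, gave 444, and the highest other 0 by limma, with at most 35 probes at an unadjusted p under 0.05, against 496. With 10 splits no share under 0.05 can be reached.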

How the results depend on the processing

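Counting control arrays 1 and 2 as 1 sample was chosen after seeing the data, and the planned fit, which kept them apart, gave 463, 338 and 480. Also chosen after seeing the data were merging 10xMIC replicates 2 and 3, the experiment code, the 2 blank features, ignored spots and the Cy3 channel alone. For MIC minus control, 26 of 31 alternatives, Cy3 alone set aside, gave counts within 1.5 times the 392 (302 to 537). For 10xMIC minus control 23 of 31 lay within 1.5 times the 239 (165 to 353), and for 10xMIC minus MIC 28 of 30 within 1.5 times the 444 (336 to 533). Similar counts need not hold the same probes. In the order of the contrasts, plain background subtraction shared 382, 238 and 439 probes with the main lists. Print-tip loess shared 254, 133 and 331, median centring 348, 184 and 403, and the deposited values 346, 189 and 399. The counts outside the ranges of 1.5 times follow in the order of the contrasts. The Cy5 channel alone gave 53 (13 higher, 40 lower), 38 and 77 (46 higher, 31 lower), and a 2-fold minimum 4, 6 and 11 by construction. The quantification day as a block gave 186 and 9 against control, with 2 residual degrees of freedom in place of 5, and the experiment code as a random block 231 and 56. For 10xMIC minus control, scaling between arrays gave 389, treated arrays against 0 gave 404 and array weights 498; the cause was not tested. The Cy3 channel alone, meant as a negative control, gave 3, 0 and 8 (limma). A single channel calls few probes, as Cy5 alone also did, so these low counts do not show an unchanged reference. At an unadjusted p under 0.05 Cy3 alone gave 127 and 69 against control (limma). Both are above 0.05 of the 789 probes, the share that the threshold alone would give. Leaving out 1 array at a time gave 238 to 504, 78 to 353 and 381 to 497, and the lowest 2 of these for the comparisons with control, 238 and 78, came without control replicate 3, where the lone control sample is assumed to vary like the other groups. The replicate block, with 3 control arrays, gave 451, 330 and 457. The replicate numbers did not pair the samples: same-numbered arrays of different groups deviated together with r from -0.08 to 0.07, and 3 of 9 arrays correlated best with their own number. Of 356 values of the named probes under alternatives, 349 kept direction and side of the threshold, 7 lost the threshold and 0 reversed. Many of these alternatives, such as leaving out an array of a group outside the contrast, cannot change the fold change. The probes were also picked as the largest changes, so these numbers overstate how stable a typical call is. A stricter flag threshold could not be run, since the files hold a single mark, and the gene list tests were not run. Signal over background was lowest on MIC replicate 2 (6.81 in Cy3), where 166 spots were too dim.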

Other observations

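The tests on 10xMIC replicates between parts of the slide, their count as 1 sample, the permutation over all offsets and the test of a shared dye effect were chosen after the result was seen; those on probes at a block offset across parts of the slide and for 10xMIC minus MIC were set before.

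Replicate 1 at 10xMIC differed from replicates 2 and 3 reproducibly, with an SD across probes of 0.23 against each, while differences between MIC replicates had an SD of 0.08 to 0.12. Spot noise is argued against, since the difference in the upper part of the slide recurred in the lower part with r = 0.693. Whether replicates 2 and 3, which share an experiment code, hold one extract on 2 slides stays open: their difference recurred with r = 0.158, lower than the 0.32 to 0.52 between MIC replicates but above that of control arrays 1 and 2. The Cy5 image name of replicate 3 carried the slide code of replicate 2, so whether both Cy5 scans come from one slide stays open too. Counted as 1 sample, replicates 2 and 3 gave 185 changed probes against control in place of 239. Another culture, extract or slide batch for replicate 1 may equally account for its distance from the others, and was not tested.

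Probes 2 block rows apart in the same place of their blocks changed together. Their fold changes correlated with r = 0.28 at MIC and 0.27 at 10xMIC over 512 pairs, the strongest at MIC of the 1083 offsets computed, with r weighted by the square root of the number of pairs, and in 1000 permutations of probes within blocks the strongest of all 1083 offsets never reached it at either dose (p = 0.001, the smallest they can give). At 1 block row apart r was -0.06 and -0.02. A local hybridization artefact is argued against, because reading one probe on the upper and the other on the lower part of the slide kept at least 0.955 of the correlation. Control slides shared by both comparisons are argued against by r = 0.298 for 10xMIC minus MIC, which uses none. A constant dye effect cancels in every contrast, so that value could not test it. Control-versus-control ratios correlated at that offset as well (r = 0.257). A candidate explanation is that probes were printed in gene order, so that such pairs are neighbours transcribed together. Probes made or amplified together could do the same, and without gene names neither was tested.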
